A study of Homo sapiens with 6 samples.

How the data were processed

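Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed in IMR90 cells, which are human lung fibroblasts, grown without treatment under low oxygen. The series held 6 samples in 3 groups of 2 replicates: chromatin precipitated with an antibody against lamin B1, a structural protein of the nuclear lamina, chromatin precipitated with an antibody against LC3, a protein that is coupled to lipid and decorates autophagosomes, and input chromatin. Per the labels' protocols, cells were crosslinked with formaldehyde, chromatin was sheared by sonication, and libraries were made from the precipitated and input DNA. A domain list was used for each of the 4 precipitated samples. Read-level files and the input libraries were not analysed here. The labels do not say whether the replicates came from separate cultures, so differences between replicates may be technical in part.

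Per the submitters' processing notes, bcl2fastq 2.16.0.10, Bowtie2 and bedtools were used and the build was GRCh37/hg19. The deposited lists are named for EDD, a caller of broad enriched domains that compares precipitated with input reads. Its version and settings, the way in which input was used and any filter on reads are not given in the sources used here. Each deposited list has 3 columns, the chromosome, start and end of each domain of 1 replicate, and no height, score or p-value. The number of reads behind each domain is therefore unknown, and no interval for counting error can be given. Domains were called separately in each replicate. All starts and ends in a list are multiples of one bin size, which was 3 kb for lamin B1 replicate 1, 4 kb for lamin B1 replicate 2, 5 kb for LC3 replicate 1 and 3 kb for LC3 replicate 2. The shortest domain in any list was 124 kb. The caller can bridge short stretches without enrichment, so domain number and length can depend on its settings as well as on the signal. No domains overlapped within a list.

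All positions were handled in steps of 1 kb with Python 3.11.15 and NumPy 2.4.6. Consensus domains of an antibody were the bases inside the lists of both its replicates. Shared regions were bases in all 4 lists, lamin B1-only regions were in both lamin B1 lists and neither LC3 list, and LC3-only regions were in both LC3 lists and neither lamin B1 list. Overlap of 2 lists was given as the Jaccard index, the bases in both divided by the bases in either. Chromosome lengths of the build were not used here, so coverage of a chromosome was expressed as a percent of its span, the stretch from the first to the last base of any domain in the 4 lists. Spans include centromeric gaps, and the span of chromosome 19 is short because it holds few domains.

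Overlap between antibodies was tested by rotation: the LC3 domains of each chromosome were shifted together by a random offset around its span, which keeps domain lengths and spacing, in 10000 rotations with a two-sided p whose smallest possible value is 0.0001. Tests that needed every domain refitted used 1000 rotations, with a smallest p of 0.001. Lamin B1 consensus domains of at least 100 kb were called covered by LC3 where at least 50% of their bases lay in LC3 consensus domains, and the lengths of covered and uncovered domains were compared by a two-sided permutation test across domains with 100000 resamples, whose smallest p is 1e-05. Correlations across chromosomes were tested with 100000 permutations. These tests treat positions, domains or chromosomes as units and do not measure variation between cultures. Values per list were compared between antibodies by exact permutation of 2 lists against 2, which cannot give a p below 0.333. P-values of related tests were adjusted by the Benjamini-Hochberg method. The rotation test was checked on simulated data. It called 7% of 100 simulated LC3 lists that were unrelated to the lamin B1 list. It called 53% of 100 lists to which a random 10% of the lamin B1 domains had been added. Simulated LC3 domains were spread over the whole span, including stretches without a domain in any real list. These rates therefore do not cover lists that avoid the same stretches. The length test called 8% of 100 simulated sets with no difference and 100% of 100 sets with a 2-fold difference.

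The tests of overlap, covered length, domain length and chromosome coverage, their alternatives except those named below and the rule for the regions to be named were chosen before the data were examined. The rule named chromosomes 18 and 19, the 3 chromosomes with the highest and the 3 with the lowest coverage by each antibody, and the 5 longest regions of each class. Alternatives covered a minimum domain length of 500 kb, autosomes only, merging of domains less than 100 kb apart, the union of replicates, random placement of LC3 domains, other overlap criteria, same-numbered pairs only and the omission of each list in turn. Removal of stretches over 1 Mb without any domain before rotation, also for the classes of lamin B1 domain length, rotation of LC3 in the length comparison and a minimum at the 10th percentile of LC3 domain length were added after the lists had been seen, as were the classes of lamin B1 domain length and the comparison of single chromosomes. For random placement, the order of the LC3 domains and the free space between them were drawn at random on each chromosome in place of the planned bedtools shuffle, because the domains fill much of each span. Planned comparisons of 23 gene lists, gene density and GC content were not made, since no genome or annotation of build GRCh37/hg19 was used here, and planned comparisons of domain scores were not made because the lists hold no score. Replicate numbers were shared between antibodies. The differences between the 2 lamin B1 lists and between the 2 LC3 lists had a correlation of 0.081 over 28402 windows of 100 kb, and the labels tie the numbers to no shared culture or day, so the lists were treated as unpaired, although more sequence separated them by replicate number (24.9 Mb) than in the crossed way (9.24 Mb).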

Results

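Domain lists from 4 ChIP-seq samples of untreated IMR90 fibroblasts were compared: 2 replicates for lamin B1 and 2 for LC3. Lamin B1 marks lamina-associated domains, long and mostly gene-poor stretches of heterochromatin that lie against the nuclear envelope. LC3 is best known from the cytoplasm, where its lipidated form sits on autophagosome membranes and binds cargo receptors. The comparison asked where in the genome LC3 was found relative to lamin B1. Only one condition was examined, and sequencing depth is unknown because the lists give positions alone.

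The lists of both antibodies held megabase-sized domains, and LC3 domains were fewer and longer. They come from a caller of broad domains, so domain size does not show whether either protein also sits at narrow sites. The lamin B1 lists held 613 domains over 1400 Mb and 593 domains over 1384 Mb, and the LC3 lists held 437 domains over 1403 Mb and 475 domains over 1484 Mb. Total length therefore averaged 1392 ± 11.1 Mb for lamin B1 and 1444 ± 57.4 Mb for LC3 (SD, n = 2 each), or 49.0% and 50.8% of the summed chromosome spans. Mean domain length was 2.31 ± 0.036 Mb for lamin B1 and 3.17 ± 0.061 Mb for LC3 (SD, n = 2 each). Median length was 1.15 Mb in both lamin B1 lists, 1.70 Mb in LC3 replicate 1 and 1.41 Mb in LC3 replicate 2. Domains over 10 Mb made up 21.3% and 23.5% of lamin B1 length but 36.8% and 42.1% of LC3 length, and the longest domain spanned 19.9 and 23.6 Mb for lamin B1 against 38.5 and 61.0 Mb for LC3. Both LC3 lists lay beyond both lamin B1 lists for domain number, total length, median length and mean length. Exact two-sided permutation of the 4 lists gave p = 0.333 for each of these 4 differences, the smallest value that 2 lists against 2 allow. The excess in total length was 51.7 Mb, which is less than the SD of the LC3 lists, and it fell to 11.2 Mb without LC3 replicate 2 and rose to 92.3 Mb without LC3 replicate 1.

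**Figure D1:**
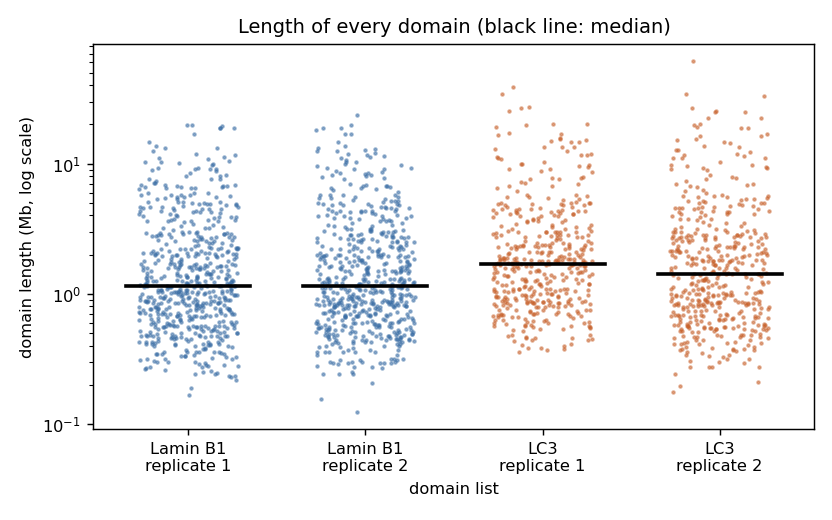
Length of each domain (Mb, log scale) in the 4 lists, with points spread sideways for visibility and a black line at the median. The medians are 1.15 Mb in both lamin B1 lists, 1.70 Mb in LC3 replicate 1 and 1.41 Mb in LC3 replicate 2.

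Replicates of one antibody located largely the same sequence. The Jaccard index was 0.882 between the lamin B1 lists and 0.837 between the LC3 lists, against 0.351 and 0.391 on average when one list was rotated along the chromosomes. The 4 pairs of a lamin B1 and an LC3 list shared fewer bases than either pair of replicates, with Jaccard indices from 0.666 to 0.740 and a mean of 0.698. Grouping the 4 lists by antibody gave a mean within-pair index of 0.860, while grouping them by replicate number gave 0.703 and the crossed grouping gave 0.694. Antibody was the best of 3 groupings, and the exact p of 0.333 is the lowest that 3 groupings allow. Of 1742 Mb in any list, 306 Mb (17.6%) separated the antibodies with both replicates in accord, whereas 24.9 Mb (1.43%) separated the lists by replicate number and 9.24 Mb (0.530%) separated them in the crossed way.

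LC3 domains lay mainly inside lamin B1 domains. Consensus domains covered 1305 Mb for lamin B1 and 1316 Mb for LC3, and 1040 Mb were common to all 4 lists. Thus 79.1% of LC3 consensus length fell in lamin B1 consensus domains, and 79.7% of lamin B1 consensus length was covered by LC3. Rotated LC3 domains had 49.6% of their length in lamin B1 domains, with the central 95% of rotations between 47.1% and 52.4% and the highest at 55.2%. The observed overlap was 1.59-fold the rotated mean, with a two-sided rotation permutation p of 0.0001, the smallest that 10000 rotations can give. When stretches over 1 Mb without a domain in any list were removed before rotation, the rotated mean rose to 70.4% and the observed share remained above it (permutation p = 0.0001). In the 4 pairs of single lists, 79.8% to 82.2% of LC3 length lay in lamin B1 domains. The mean Jaccard index of these pairs, 0.698, compared with 0.365 under rotation and a permutation p of 0.0001. Counted by domain, 347 of 422 LC3 consensus domains (82.2%) had at least 50% of their length in lamin B1 domains, and 50 domains (11.8%) shared no base with them. A single LC3 consensus domain usually met a single lamin B1 domain: 317 touched one and 55 touched 2 or more. The LC3 domain with the most, on chromosome 1 from 65770001 to 91325000, ran over 7 lamin B1 domains. Rotation tests describe positions in the genome and not variation between cultures.

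**Figure D2:**
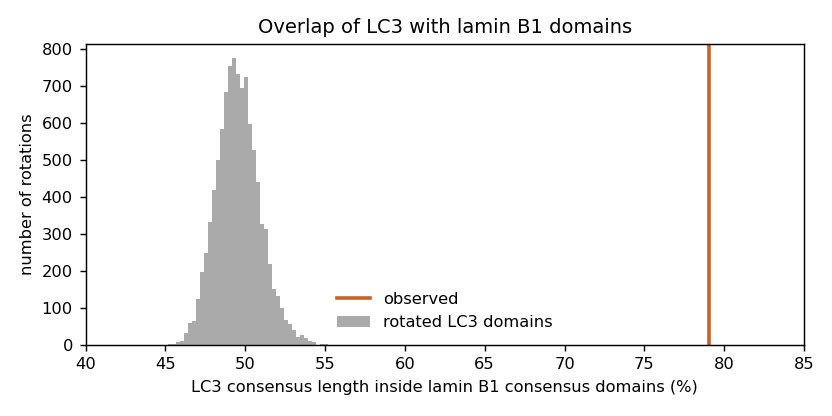
Percent of LC3 consensus length inside lamin B1 consensus domains, observed (vertical line) and for 10000 rotations of the LC3 domains along their chromosomes (grey bars, number of rotations). The observed 79.1% lies to the right of all rotations, which reach 55.2% at most.

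Sequence in all 4 lists formed the longest regions, and sequence in the lists of only 1 antibody was scattered in shorter pieces. Regions of only 1 antibody are what remains outside the overlap of long domains, so short pieces follow in part from their definition. Shared regions numbered 470 with a median length of 1.27 Mb. The longest were on chromosome 13 from 53493001 to 73248000 (19.8 Mb), chromosome 5 from 98424001 to 118173000 (19.7 Mb), chromosome 7 from 108204001 to 127074000 (18.9 Mb), chromosome 4 from 90080001 to 108728000 (18.6 Mb) and chromosome 3 from 73320001 to 90220000 (16.9 Mb), all in GRCh37/hg19. Lamin B1-only sequence amounted to 126 Mb, or 7.26% of the bases in any list, in 254 stretches. Of these, 175 were at least 100 kb long, with a median of 0.429 Mb. The longest were on chromosome 12 from 125664001 to 131450000 (5.79 Mb), chromosome 5 from 23055001 to 27255000 (4.20 Mb), chromosome 8 from 2100001 to 5904000 (3.804 Mb), chromosome 16 from 60472001 to 63807000 (3.34 Mb) and chromosome 7 from 144380001 to 147596000 (3.22 Mb). LC3-only sequence amounted to 180 Mb (10.3%) in 365 stretches, of which 235 were at least 100 kb long, with a median of 0.611 Mb. The longest were on chromosome 3 from 148584001 to 152144000 (3.56 Mb), chromosome 1 from 84447001 to 87546000 (3.10 Mb), chromosome 6 from 52116001 to 55212000 (3.10 Mb), chromosome 3 from 111344001 to 113886000 (2.54 Mb) and chromosome 4 from 108840001 to 111240000 (2.40 Mb). The last of these lay just beyond the end of the shared region named on chromosome 4. Genes in these regions were not analysed here.

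**Figure D3:**
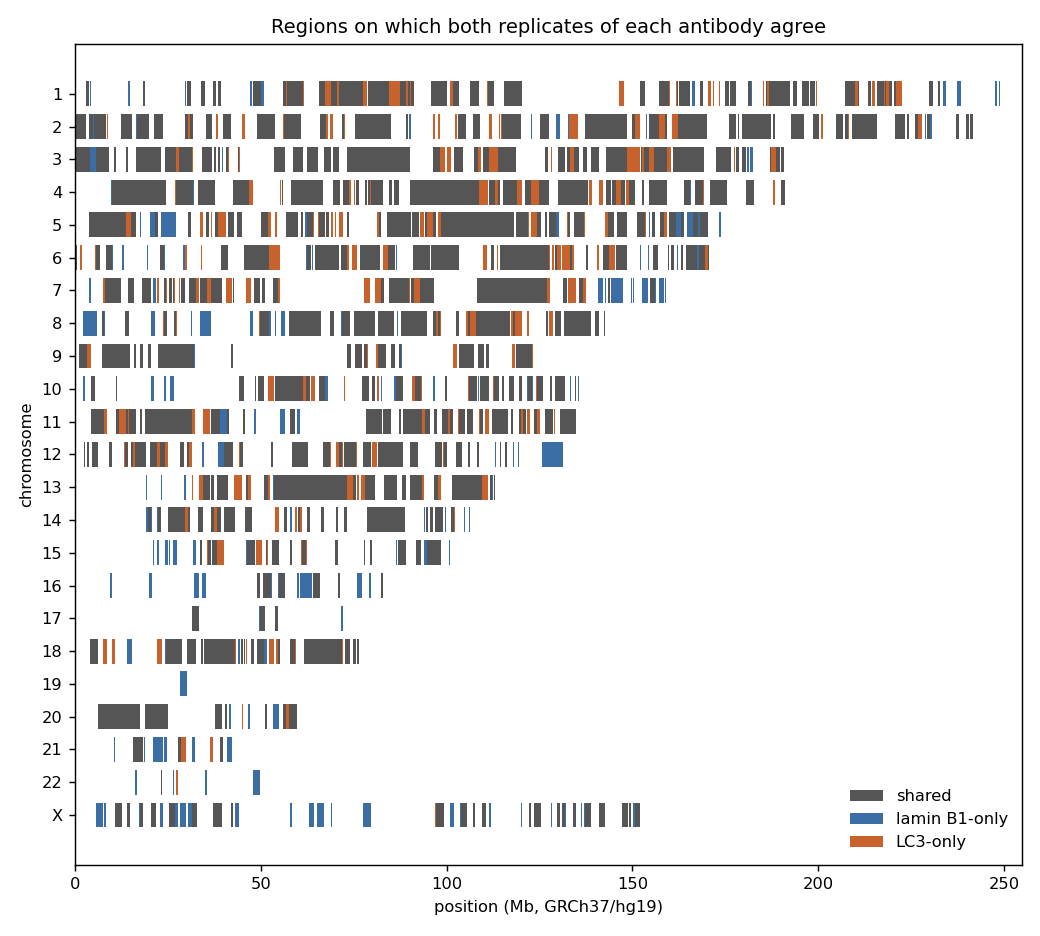
Map of the regions in all 4 lists (grey), in both lamin B1 lists and neither LC3 list (blue) and in both LC3 lists and neither lamin B1 list (orange) along each chromosome, with position in Mb of GRCh37/hg19. Shared regions fill 1040 Mb, and chromosome X has 18.3 Mb of lamin B1-only sequence.

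LC3 covered long lamin B1 domains more often than short ones. Of 597 lamin B1 consensus domains, 437 (73.2%) were covered by LC3 over at least 50% of their length, 250 of them entirely, and 141 contained no LC3 base. The median length was 1.35 Mb for the 437 covered domains (interquartile range 0.760 to 2.75 Mb). It was 0.780 Mb (0.434 to 1.46 Mb) for the 160 others, which had LC3 on less than 50% of their length or none. The 1.74-fold difference had a permutation p of 1e-05 across domains, the smallest that 100000 resamples can give. Among domains under 0.5 Mb, 53 of 100 were covered, against 44.5% on average for rotated LC3 domains (rotation permutation p = 0.12, adjusted over the 5 length classes p = 0.12). Coverage reached 71.4% of 168 domains between 0.5 and 1 Mb, 75.2% of 149 between 1 and 2 Mb, 86.3% of 117 between 2 and 5 Mb, and 81.0% of 63 above 5 Mb. Each of these last 4 classes exceeded its rotations, which averaged 44.3% to 52.8%, at a permutation p of 0.001 (adjusted p = 0.0013). Rotation was also run without stretches over 1 Mb that hold no domain, with rotated means of 68.2%, 70.7%, 67.7%, 74.9% and 80.3% from the shortest to the longest class. Those stretches were picked from the same 4 lists, and their removal raised every rotated mean. A class below its rotated mean is therefore not evidence that LC3 avoids such domains. By this permutation test of rotated LC3 positions, coverage was lower than rotated under 0.5 Mb (adjusted p = 0.0025), higher from 1 to 2 Mb (adjusted p = 0.042) and from 2 to 5 Mb (adjusted p = 0.0025), and not detectably different from 0.5 to 1 Mb or above 5 Mb (adjusted p = 1 for both). The 1.74-fold length difference compared with 1.15-fold on average in these rotations (central 95% 0.906 to 1.38, permutation p = 0.001). When at least 80% of a domain had to be covered, the length difference shrank to 1.27-fold (permutation p = 0.045), and it grew to 2.12-fold when a single base was enough. The cutoff alone can move this difference, since a long domain meets a single base more easily and reaches 80% less easily. Rotation was not run at these 2 cutoffs.

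**Figure D4:**
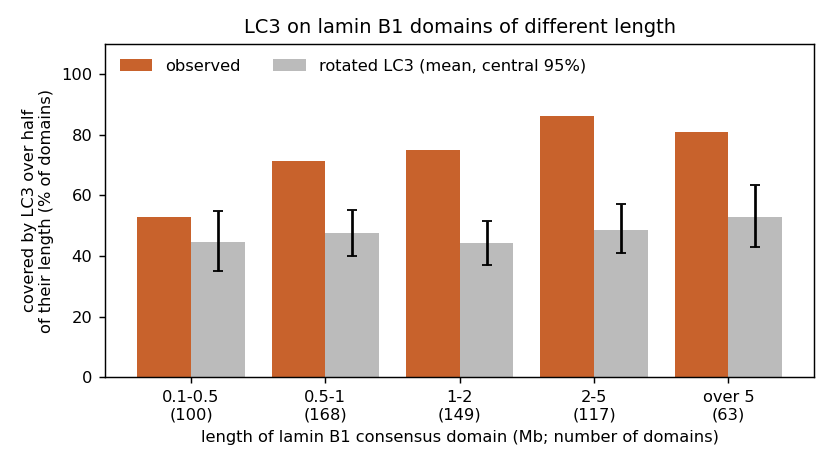
Percent of lamin B1 consensus domains covered by LC3 over at least 50% of their length, by domain length in Mb (number of domains in brackets), observed (orange) and for 1000 rotations of LC3 (grey, mean with bars for the central 95%). Rotation is along the whole span, stretches without domains included. Observed coverage is 53% under 0.5 Mb, within the rotations, and 86.3% between 2 and 5 Mb, above them.

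Chromosomes rich in lamin B1 domains were rich in LC3 domains. Across 23 chromosomes, the percent of the span in lamin B1 and in LC3 domains had a Pearson r of 0.919 and a Spearman rho of 0.891 (permutation p = 1e-05 for both, also after adjustment over 4 correlations). Without chromosomes 17 and 22, the farthest from the median, r was 0.889, and over the 22 autosomes it was 0.969. Chromosomes are not independent replicates. Chromosome 4 had the highest coverage, 65.6 ± 0.66% for lamin B1 and 74.6 ± 6.5% for LC3 (SD, n = 2 each). Chromosomes 5 and 3 followed for lamin B1 with 61.8% and 60.9%, and chromosomes 13 and 3 for LC3 with 71.0% and 70.7%. Gene-poor chromosome 18 carried 44.4 ± 2.7 Mb of lamin B1 domains and 49.6 ± 0.097 Mb of LC3 domains (SD, n = 2 each). Gene-dense chromosome 19 carried 3.53 ± 0.71 Mb and 1.13 ± 1.6 Mb, and LC3 replicate 2 listed 0 domains there. The lowest percents of span were found on chromosomes 17, 22 and 19 for both antibodies, at 11.7%, 13.97% and 22.5% for lamin B1 and 9.90%, 4.82% and 7.17% for LC3. The order of these chromosomes depends on their spans, which were 67.2, 34.1 and 15.7 Mb. In Mb, chromosome 19 carried the least of both antibodies. Chromosome 22 carried 4.76 Mb of lamin B1 and 1.64 Mb of LC3 domains, and chromosome 17 carried 7.89 and 6.65 Mb.

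The balance between the proteins differed from one chromosome to another. Both LC3 lists exceeded both lamin B1 lists on 11 chromosomes (1, 2, 3, 4, 5, 6, 7, 9, 11, 13 and 18), and both fell short of them on 7 (8, 15, 16, 19, 21, 22 and X). Exchangeable lists would give 3.83 of the 23 chromosomes each way on average. All chromosomes come from the same 4 lists and are not separate draws, so the counts are descriptive and were not tested against this number. The largest excess of LC3 was 18.98 Mb on chromosome 3. On chromosome 16, LC3 covered 9.61 ± 2.4 Mb and lamin B1 20.5 ± 2.9 Mb (SD, n = 2 each). Chromosome X had 85.9 and 91.5 Mb of lamin B1 domains in the 2 replicates and 31.7 and 66.6 Mb of LC3 domains. LC3 consensus domains covered 35.7% of the lamin B1 consensus length on X and 82.5% on the autosomes as a whole. Chromosomes 19, 22 and 21 had lower values than X, 0%, 11.99% and 32.8%, and chromosome 16 had 39.1%, so X did not stand apart from every autosome on this measure. With LC3 replicate 1 left out, the values for X and the autosomes were 75.1% and 89.0%, so the size of the gap rests largely on that replicate. The LC3 replicates had a Jaccard index of 0.420 on X and 0.857 on the autosomes, while the lamin B1 replicates had 0.788 and 0.889. Summed over autosomes, LC3 covered 91.3 Mb more than lamin B1, whereas on X the means were 49.1 Mb for LC3 and 88.7 Mb for lamin B1. With 2 lists against 2, no exact test on a single chromosome can give a p below 0.333.

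**Figure D5:**
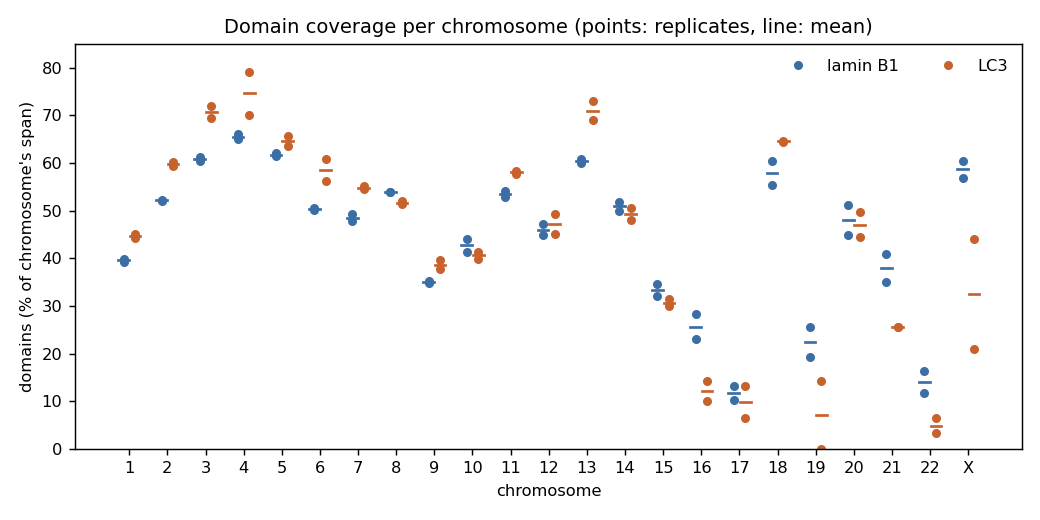
Percent of each chromosome's span in lamin B1 (blue) and LC3 (orange) domains, with a point per replicate and a line at the mean of the 2 replicates. On X the lamin B1 lists cover 56.9% and 60.5%, and the LC3 lists cover 21.0% and 44.1%.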

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

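Of 73 values under alternative settings, 70 kept their call. The call was direction and side of the 0.05 threshold, except for 8 values of total covered length, which have no p-value. Some settings, such as random placement, change only the expected value and leave the observed one as it was. The other 3 were classes of lamin B1 domain length after removal of stretches over 1 Mb without any domain: the 53% covered under 0.5 Mb went from above to below the rotated mean, and the 71.4% from 0.5 to 1 Mb and the 81.0% above 5 Mb no longer differed from it. For total covered length, which no exact test can call, no value moved by more than the combined SD of the lists, 58.4 Mb. The main excess of 51.7 Mb is smaller than that SD, so even a fall to no excess would have kept the call. These 8 values are thus a weak check, and they ranged from 11.2 to 92.3 Mb. The covered-length value with same-numbered pairs equals the main value by construction. The share of LC3 length inside lamin B1 domains ranged from 76.1% to 83.5%, both with 1 list left out, and the share of lamin B1 length inside LC3 domains from 77.0% without lamin B1 replicate 2 to 88.5% with the union of replicates. Counted as a percent of domains instead of length, 67.3% of LC3 domains shared at least 50% of both partners with a lamin B1 domain (12.9% under rotation) and 88.2% shared at least 1 base (74.1% under rotation), against 47.6% (9.04% under rotation) and 76.4% (65.1% under rotation) of lamin B1 domains. With each list left out in turn, the mean Jaccard index lay between 0.672 and 0.725. With the replicate block, that is, same-numbered pairs only, the Jaccard index was 0.703 and the shares were 81.0% and 84.1%; the block changed no call. The excess of LC3 in covered length was 91.3 Mb on autosomes alone. The length difference between lamin B1 domains with and without LC3 ranged from 1.27-fold to 2.12-fold, both at other cutoffs for coverage, which can move it by themselves. The minimum of 100 kb removed no domain, so that setting tests nothing. Placing LC3 domains at random gave an expected share of 49.5%, close to that of rotation. Removing stretches over 1 Mb without any domain before rotation (expected share 70.4%), also in the length comparison (permutation p = 0.001) and its classes, rotating LC3 in the length comparison (permutation p = 0.001) and restricting that comparison to domains at least as long as the 10th percentile of LC3 length (1.30-fold, permutation p = 0.022) were added after the lists had been seen. Stricter domain scores, gene lists, gene density and GC content were not run. The unknown depth limits what the absence of a domain from a list can show.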

Other observations

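The tests of bin size, of LC3 on long uncovered domains, of chromosome X, of the ratio of coverage across chromosomes, of chromosome ends, of domain edges and of neighbour distance were chosen after related results were seen. The tests of shared input noise, of stretches without any domain, of gaps between lamin B1 domains and of a minimum length were added after the lists had been seen, with their bounds written down before their own results.

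The edges of LC3 domains fell near edges of lamin B1 domains more often than under rotation. In the 4 pairs of lists, 45.3% to 54.4% of LC3 edges lay within 100 kb of a lamin B1 edge, against 8.35% to 8.72% on average when one list was rotated (permutation p of 0.001 in each of the 4 pairs, the smallest that 1000 rotations can give). Between replicates, 61.4% and 66.5% of LC3 edges and 73.8% and 76.2% of lamin B1 edges had such a match. From the other side, 33.4% to 43.5% of lamin B1 edges had an LC3 edge within 100 kb. The median distance was 76.5 to 121.5 kb from LC3 edges to the nearest lamin B1 edge, and 172.5 to 367 kb from lamin B1 edges to the nearest LC3 edge. Edges were not compared with rotation that leaves out stretches without any domain. Lamin B1 domains with and without LC3 did not differ detectably in their distance to the nearest other lamin B1 domain, with medians of 924 and 915 kb (permutation p = 0.89 across 597 domains).

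Overlap of LC3 with lamin B1 was weighed against 2 technical explanations. Noise from input libraries shared by same-numbered samples should raise the overlap of same-numbered lists, but their mean Jaccard index exceeded that of crossed lists by 0.0084, under the bound of 0.02 set beforehand. More sequence separated the lists by replicate number than in the crossed way, 24.9 against 9.24 Mb, so a small shared part is not excluded, and an input pooled over replicates would escape this test. Common avoidance of long stretches without any domain, such as unassembled sequence, was tested by removing every such stretch over 1 Mb (978 Mb in all). Rotation then gave 70.4% on average and 73.0% at most, and the observed 79.1% stayed above it (permutation p = 0.0001). Common avoidance of these stretches therefore did not account for all of the overlap. The stretches were defined by the same lists, so the test cannot tell unassembled sequence from sequence that both proteins lack. It gives no technical part of the overlap.

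LC3 domains were coarser than lamin B1 domains, being longer, fewer and less often present on short lamin B1 domains. With equal bins of 3 kb, LC3 replicate 2 had a mean domain length 1.37 times that of lamin B1 replicate 1 (bootstrap 95% interval over domains 1.13 to 1.65). This sets 1 list against 1 and gives no spread between samples. Mean length was 2.28 Mb at 3 kb and 2.33 Mb at 4 kb for lamin B1, and 3.12 Mb at 3 kb and 3.21 Mb at 5 kb for LC3. Mean length was thus longer for LC3 at 3 kb than for lamin B1 at 3 or 4 kb. The bound against bin size required more than 1 pair of lists with equal bins, and only 1 pair had them. Bin size therefore stays open as a source of the difference in mean length. It stays open for the median too, which was 1.23 times as long at equal bins. LC3 had a median of 1.41 Mb at 3 kb and 1.70 Mb at 5 kb. Another explanation is that LC3 domains run across gaps between lamin B1 domains. Gaps between lamin B1 domains touched by the same LC3 domain held 42.4% of LC3-only sequence, between the bounds set for and against this explanation. A further 40.3% lay at outer edges and 17.3% in LC3 domains that touched no lamin B1 domain. Failure to call short LC3 domains also stays open: among 450 lamin B1 domains of at least 648 kb the covered ones were still 1.30 times longer (interval 1.10 to 1.55), but such domains lacked LC3 in 12.5% to 20.7% of cases over the 4 pairs of lists and in 20.9% between consensus domains, while LC3 replicate 2 missed 8.65% of LC3 replicate 1 domains and LC3 replicate 1 missed 12.6% of LC3 replicate 2 domains, so every pair exceeded the first of these and the lowest pair did not exceed the second. A wider spread of LC3 along the chromosome may also contribute, and it cannot be told apart from the caller's joining of gaps without the read signal.

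Chromosome X had less LC3 than its lamin B1 coverage would place it among autosomes. LC3 replicate 2 on X departed from the autosomal line by -21.7 percentage points (autosomes between -14.2 and 14.4), and replicate 1 departed further, by -42.4. On this measure alone, replicate 2 argues against a fault limited to LC3 replicate 1. The measure was chosen after related results were seen. By the share of lamin B1 consensus length that LC3 covered, the gap was smaller with LC3 replicate 1 left out, 75.1% on X against 89.0% on the autosomes. Lamin B1 covered 58.7% of X against an autosomal median of 48.3%, so domains of both antibodies were not scarce there. Coverage does not measure how reliably domains are called. Replicates shared less on X than on the autosomes, with Jaccard indices of 0.788 against 0.889 for lamin B1 and 0.420 against 0.857 for LC3. A general difficulty in calling domains on X therefore stays open. Across the 22 autosomes the ratio of LC3 to lamin B1 coverage rose with lamin B1 coverage even when the coverage came from lamin B1 replicate 1 and the ratio from replicate 2 (Spearman rho 0.668, permutation p = 0.001; Pearson r 0.683, and 0.711 without chromosomes 17 and 22), and 0.733 with the replicates exchanged. A weaker LC3 signal on X that sits near the calling threshold, and a biological difference of X, both stay open as hypotheses.

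A further hypothesis, drawn from the map of regions, is that lamin B1 domains near chromosome ends lack LC3. Of 112 lamin B1 consensus domains centred within 10 Mb of an end of the chromosome span, 49 (43.8%) lacked LC3, against 111 of 485 elsewhere (22.9%). The difference of 20.9 percentage points had a p of 0.0022 by permutation within chromosomes and 0.027 by rotation of LC3, and it was 23.7 points among domains of at least 1 Mb. It was 10.8 points without LC3 replicate 2 (permutation p = 0.15) and between 20.7 and 26.0 points without each of the other lists, so the call rests on that replicate and the hypothesis remains undecided. Ends of the span are not telomeres on chromosomes whose short arm holds no domain.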
